A study of Drosophila melanogaster with 30 samples.

How the data were processed

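RNA of Drosophila melanogaster pupae and young adults was measured on 30 spotted arrays with 2 channels each, in 6 experiments. Each array compared 2 samples directly, 1 labelled with Cy5 and 1 with Cy3, and each experiment held both dye orientations in equal number. The whole-body experiment compared males lacking the fru P1 transcripts, which encode the male-specific transcription factor FRUM, with wild-type males at 48 h after puparium formation on 8 arrays. The same comparison was made in the dissected central nervous system (CNS) on 6 arrays, and males were compared with females of the Canton S strain in the CNS on 4 arrays. Males carrying an RNA interference (RNAi) construct against the A isoform of the ecdysone receptor (EcR-A), driven by fru P1-GAL4, were compared with males carrying the driver alone on 4 arrays each at 0 h, at 48 h and in adults of up to 24 h. The 0 h sample was brain and ventral nerve cord, and the labels name brain for the other time points, although their titles say CNS. Per the series' design text the samples were independent biological samples.

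Per the labels' protocols, cDNA of whole pupae was labelled directly during reverse transcription, whereas CNS RNA was amplified and labelled as cRNA, so the whole-body and CNS arrays differ in tissue and in labelling. Per the submitters' processing notes the authors used limma; its version, the background correction and the normalization are not given in the sources used here. The deposited table held 1 value per probe and array, with missing cells, for 15744 probes after 32 control spots were left out; 1903 probes had no value on any array. On 27 arrays the deposited values had the form of normalized log2 ratios, with a median between -0.08 and 0.041 and a standard deviation (SD) over probes between 0.352 and 0.689. On the other 3 arrays, replicates 2, 3 and 4 of the EcR-A RNAi experiment at 48 h, the SD was 2.67, 2.21 and 1.41 and values ran from -17.7 to 18.1. The authors' deposited values on these 3 arrays were therefore treated as a score of unknown scale, and no fold change from them is reported. Background and spot intensities were not used here, so signal over background is unknown. The number of arrays limits the precision.

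The labels give the dye of each sample but not the direction of the deposited ratios. In the sex experiment 22 of 23 probes beyond 1 log2 unit on every array had the same sign in both dye orientations, and in the whole body 16 of 17 did in 1 allele pair and 22 of 24 in the other. The ratios were thus read as already turned to 1 direction within an experiment. In the fru CNS experiment and the RNAi experiments at 0 h and in adults too few probes passed that limit to decide it (0 of 2, 0 of 1 and 0 of 6 had 1 sign, whereas 2 of 2, 0 of 1 and 5 of 6 followed the dye orientation). The reading there rests on the component that follows the dye orientation. That component correlated across probes between the CNS experiments on the log2 scale with Pearson's r between 0.346 and 0.696, and between the whole-body allele pairs with r = 0.676. A dye bias would do this whichever samples were compared. If the CNS ratios ran Cy5 over Cy3, however, the component would hold the effects themselves. The correlation does not exclude that, so the reading in these experiments stays an assumption. Under this reading a positive ratio in the CNS experiments likely has the same sense for mutant over wild type, female over male and RNAi over control, or for all of these reversed. The whole-body dye component correlated with those of the log2 CNS experiments with r between 0.0378 and 0.195, so the direction of the whole-body ratios is not tied to that of the CNS ratios. The series' design text names males, wild type and RNAi first in its comparisons, an order which, if it were that of the ratios, would set RNAi opposite to the other CNS experiments. The labels do not settle any of this, so signs below are those of the deposited ratios. Reading the ratios as Cy5 over Cy3 on every array was run as an alternative.

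Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Each experiment had 1 coefficient for its effect and 1 for dye. A probe was tested where at least 75% of the experiment's arrays had a value, with at least 1 in each dye orientation. The dye coefficient takes up the gap between dye orientations, so the SEs and p-values do not measure that gap. Where only 1 array of an orientation had a value, that array was fitted exactly. The design chosen before the data were examined put all 22 CNS and brain arrays into 1 fit, so that they shared an estimate of the spread. Because 3 of these arrays were not on a log2 scale, the other 18 arrays on the log2 scale of the 4 remaining CNS experiments were fitted together, and the 48 h RNAi experiment was fitted alone on its 4 arrays. Setting these arrays apart was decided before any test was run, but the fit of the 48 h experiment was settled after both of its counts were known. The 22-array fit is given as an alternative. That fit mixes the scales in 1 estimate of the spread, so its counts are not like for like with those of the main fits. The whole-body arrays were fitted separately. The allele pairs used in the fru experiments, fru-440/fru-P14 and fru-w12/fru-ChaM5, were averaged in the main whole-body test, and a second fit gave each pair its own effect and tested the difference. In the CNS each pair had 1 dye orientation only, so pair and dye cannot be told apart within those arrays. Differences between RNAi time points were tested as contrasts. Those with 48 h used the 22-array fit as designed and mix the scales, so their counts are not read as expression.

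No pair of arrays held identical values, and the most alike, replicates 2 and 3 of the fru CNS experiment, correlated with r = 0.759.

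Probes were to be named as the 10 largest positive and 10 largest negative calls per comparison with the same sign on every array. The files used here do not pair probe IDs with gene names, and 0 IDs matched the reference gene table, so at most 2 IDs per direction are printed and calls are counted per probe. For the same reason the lists of genes fixed beforehand, averages over the probes of a gene and a check of direction by the male-specific roX RNAs were not analysed here. The tests of each experiment, of the difference between allele pairs and of adult against 0 h were run on simulated data. These data had the real missing values and spreads, with 200 probes changed in each of 10 repeats. The contrasts with 48 h and the effects of each allele pair were not simulated. Of changes of 1 log2 unit the fit recovered 95.1% between the sexes (7414 probes run), 99.1% in the whole body (7051), 98.4% in the fru CNS experiment (7461), 97.6% for RNAi at 0 h (5934) and 97.3% in adults (5992). For the difference between allele pairs it was 86% and for adult against 0 h 82.4%. In the 48 h RNAi experiment (4302) it recovered 1.52% of changes of 2 units. False calls made up between 3.1% and 7.4% of all calls in these runs, and 25% of the few in the 48 h experiment. These shares describe the simulated data only. The real counts moved when 1 array was left out, as given below, so the shares do not measure how far the real calls can be relied on. Alternatives covered the dye term, centring, scaling, robust estimation, array weights, missing values, thresholds, the samples in the fit and each array left out.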

Results

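The series held 30 arrays of 2 channels in 6 experiments: males against females in the CNS (4 arrays), fru P1 mutant against wild-type males in the whole body (8) and in the CNS (6), and EcR-A RNAi against control males at 0 h, 48 h and in adults (4 each). Each array gave a value for between 3934 and 11533 of the 15744 probes. The number of arrays limits the precision, and signal over background is unknown. Values are log2 ratios with the sign in which they were deposited; which sample a positive ratio favours is not settled by the labels, and the whole-body signs are not tied to those of the CNS. Probes carry plate positions as IDs, which the files do not pair with gene names.

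**Figure D1:**
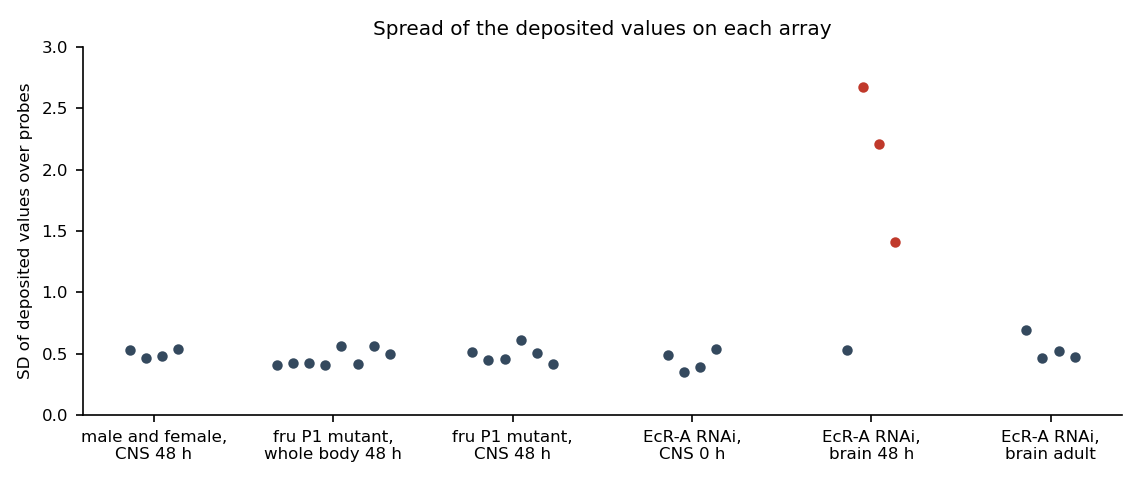
Standard deviation over probes of the deposited values, with 1 point per array, grouped by experiment on the horizontal axis. Replicates 2, 3 and 4 of the EcR-A RNAi experiment at 48 h (red) stand at 2.67, 2.21 and 1.41, and the other 27 arrays between 0.352 and 0.689.

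The first comparison asked which transcripts differ between the male and the female CNS at 48 h after puparium formation, midway through metamorphosis. Of 7414 probes tested, 45 differed between the sexes, 6 with a positive and 39 with a negative ratio, so the calls lay mostly on 1 side. The differences were large: 5 of the positive and 29 of the negative calls exceeded 2-fold, and the median size of a call was 1.5 log2 units. Probe DAC029L10 had a log2 ratio of -2.73 ± 0.17 (SE, n = 4 arrays, 6.63-fold, limma adjusted p = 5.14e-07), with values between -3.43 and -2.04 on the 4 arrays. Probe DAC039P17 stood at -2.77 ± 0.503 (SE, n = 3, adjusted p = 0.0466 by limma), but its call ended in 5 of 10 alternatives. Among them was the fit without replicate 1 (limma adjusted p = 0.0671), an array on which DAC039P17 had no value, so its effect did not move there. On the positive side, DAC006G05 had 1.76 ± 0.22 (SE, n = 4, 3.38-fold, limma adjusted p = 0.00231), and DAC003P12 had 2.07 ± 0.194 (SE, n = 3, adjusted p = 0.00103 by limma), although 1 array at 3.76 lay far above its others at 0.133 and 0.651. That array was alone in its dye orientation, so the SE of DAC003P12 does not hold this gap. Of the 45 probes, 43 had the same sign on every array with a value. The count is not well fixed by 4 arrays: 14 probes passed among those with at least 2 values in each dye orientation, 12 passed without replicate 1 and 17 without replicate 3. Part of this is loss of values: these fits still tested 28, 30 and 31 of the 45 and called 14, 5 and 8 of them. The designed fit of all 22 CNS and brain arrays called 6. Reading the ratios as Cy5 over Cy3, which the strongest probes of this experiment go against, gave 794.

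**Figure D2:**
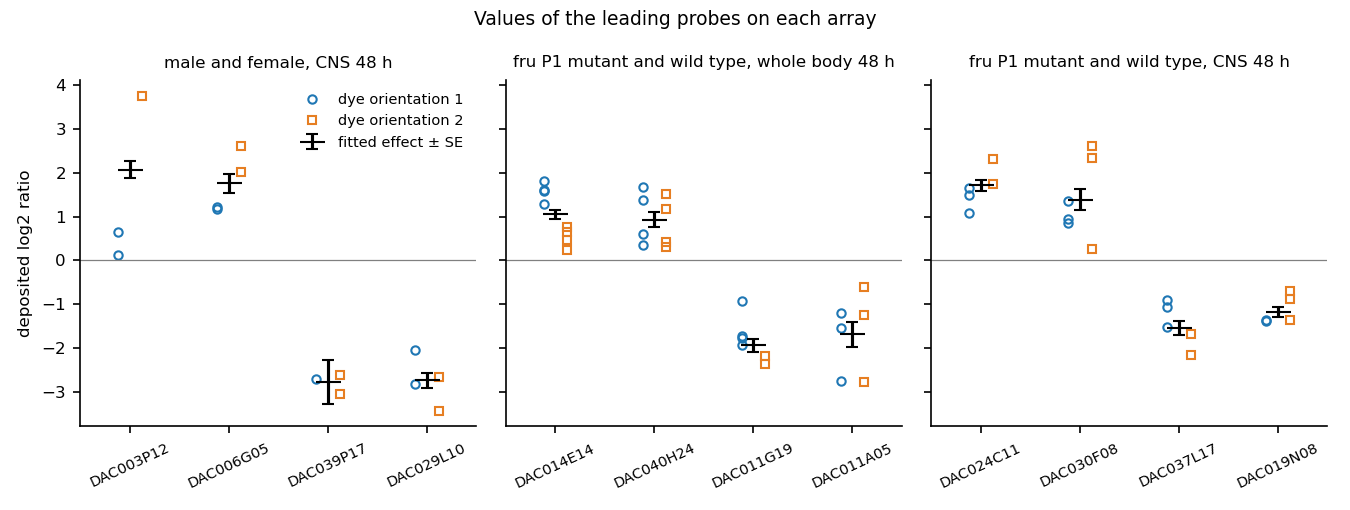
Deposited log2 ratio of the leading probes in the sex, whole-body fru and CNS fru experiments, with 1 symbol per array, circles and squares for the dye orientations, and the fitted effect with its standard error in black. DAC029L10 lies between -3.43 and -2.04 on all 4 arrays of the sex experiment, and DAC014E14 between 0.238 and 1.82 on all 8 whole-body arrays.

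The second comparison asked which transcripts depend on fru P1 in the whole male pupa at 48 h. Averaged over both allele pairs, 101 of 7051 probes differed between mutants and wild type, 29 with a positive and 72 with a negative ratio. Probe DAC011G19 had a log2 ratio of -1.94 ± 0.15 (SE, n = 6, 3.83-fold, limma adjusted p = 0.00178) and was negative on all 6 arrays that measured it. It stood at -1.80 ± 0.19 (SE) in the fru-440/fru-P14 pair and -2.07 ± 0.19 (SE) in the fru-w12/fru-ChaM5 pair. Probe DAC011A05 had -1.68 ± 0.284 (SE, n = 6, limma adjusted p = 0.0277). DAC014E14 was positive on all 8 arrays, at 1.05 ± 0.0924 (SE, n = 8, 2.07-fold, limma adjusted p = 0.00165), and DAC040H24 likewise, at 0.93 ± 0.174 (SE, n = 8, adjusted p = 0.0277 by limma). The call of DAC040H24 ended in 7 of 19 alternatives, with limma adjusted p of 0.0835, 0.0705, 0.0924, 0.0507 and 0.0765 without replicate 2, 3, 5, 6 or 7. Of the 101 calls, 81 kept 1 sign on every array. With a covariate for the allele pair the count was 378, which held all 101 of these probes. With 1 array left out it was 45 without replicate 2, 54 without replicate 6, 56 without replicate 5, 58 without replicate 7 and 66 without replicate 3. Reading the ratios as Cy5 over Cy3, which the strongest probes of both allele pairs go against, gave 62.

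The allele pairs themselves were far apart. The fru-440/fru-P14 mutants were compared with Canton S males and the fru-w12/fru-ChaM5 mutants with males of the strain w; Berlin, so the pairs differ in both lesions and controls. In the fru-440/fru-P14 pair 366 probes differed from wild type (192 positive, 174 negative), and in the fru-w12/fru-ChaM5 pair 1405 did (525 positive, 880 negative). The fru effect differed between the pairs for 1217 of 7051 probes, 820 with a higher and 397 with a lower ratio in the fru-440/fru-P14 pair. Probe DAC034F02 was 25.2-fold apart in the fru-w12/fru-ChaM5 pair (log2 ratio 4.65 ± 0.209, SE, n = 4; limma adjusted p = 1.72e-06), against -0.73 ± 0.209 (SE, n = 4) in the fru-440/fru-P14 pair, where limma gave an adjusted p of 0.0797. Whether it measures a marker gene that the stocks carry was not examined. DAC012O21 stood at 2.15 ± 0.101 (SE) in the fru-w12/fru-ChaM5 pair and -1.21 ± 0.101 (SE) in the fru-440/fru-P14 pair. In the opposite sense, DAC032I05 stood at 3.10 ± 0.151 (SE) in the fru-440/fru-P14 pair and -0.71 ± 0.151 (SE) in the other, and DAC037E21 at 3.08 ± 0.227 and -1.14 ± 0.268 (SE). The difference passed for all 4 probes (limma adjusted p between 1.93e-06 and 0.000288). Of the 160 probes called in both pairs, where independent lists would share 72.9 (Fisher's exact test p = 2.16e-26), 56 had the same sign and 104 the opposite sign. Both lists come from 1 fit and share each probe's estimate of the spread. With each pair fitted alone they shared 142 probes, against 53.2 (52 of the same and 90 of the opposite sign), although probes of low spread can still enter both lists more often. Across probes the effects correlated with Pearson's r = -0.0955 and Spearman's rho = -0.227; probes are not independent replicates. Without replicate 1 or 4 the difference passed for 765 and 771 probes. The fru-440/fru-P14 count lay between 149 and 196 without any 1 of its own 4 arrays, and the fru-w12/fru-ChaM5 count was 827, 850 and 853 without replicate 5, 6 or 7.

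**Figure D3:**
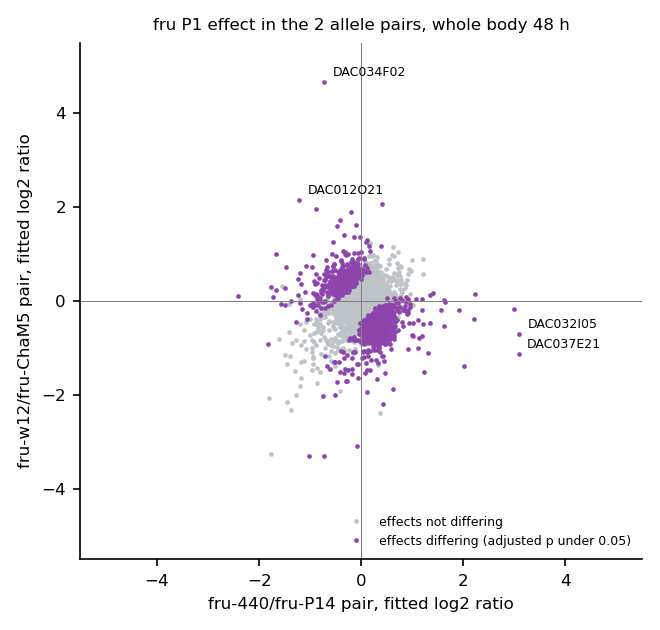
Fitted log2 ratio of fru P1 mutants against wild type in the whole body, with 1 point per probe, for the fru-440/fru-P14 pair (horizontal) and the fru-w12/fru-ChaM5 pair (vertical). The 1217 probes whose effect differed between the pairs are purple and lie mainly off the diagonal, with DAC034F02 highest at 4.65.

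In the CNS, 64 of 7461 probes differed between fru P1 mutant and wild-type males, 37 with a positive and 27 with a negative ratio. Each allele pair had 1 dye orientation only here, so the dye coefficient also takes up the difference between the pairs. The SEs and p-values do not measure that difference, and a probe changed in 1 pair only can pass. In the main whole-body test the difference between pairs entered the error, so the 64 and 101 calls come from unlike tests. Probe DAC024C11 had a log2 ratio of 1.72 ± 0.124 (SE, n = 5, 3.3-fold, limma adjusted p = 6.6e-05), with values between 1.08 and 2.32 on the 5 arrays that measured it. DAC030F08 had 1.39 ± 0.232 (SE, n = 6, 2.63-fold, limma adjusted p = 0.0121), but its call ended in 8 of 16 alternatives, with limma adjusted p of 0.0662, 0.0695, 0.059 and 0.0608 without replicate 2, 3, 4 or 5. DAC037L17 stood at -1.54 ± 0.157 (SE, n = 5, 2.9-fold) and DAC019N08 at -1.18 ± 0.118 (SE, n = 5, 2.26-fold), each with a limma adjusted p of 0.00274. In the whole body, whose sign is not tied to that of the CNS, DAC037L17 stood in the fru-440/fru-P14 pair at -1.49 ± 0.186 (SE, limma adjusted p = 0.002), and at -0.09 ± 0.186 (SE) in the fru-w12/fru-ChaM5 pair, and the difference between the pairs passed (limma adjusted p = 0.00631). Of the 64 calls, 48 had 1 sign on every array. The count ranged between 17 and 200 with 1 array left out: it was 17 without replicate 2, 3 or 4, 31 without replicate 5, 169 without replicate 6 and 200 without replicate 1. The designed fit of 22 arrays called 1, and reading the ratios as Cy5 over Cy3, which the strongest probes of this experiment do not exclude, gave 1941.

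The fru effects in the whole body and in the CNS had a Spearman's rho of -0.0323 across the 4841 probes tested in both (jackknife SE over arrays 0.09). Because the relative direction of these experiments is open, shared calls of like and of opposite sign would change places with 1 of them turned. Of the calls, 1 probe was positive in both tissues, where independent lists would share 0.118, and 0 were negative in both. DAC011A05 was 1 of 4 probes that were negative in the whole body and positive in the CNS, against 0.31 for independent lists (Fisher's exact test p = 2.26e-04, adjusted p = 0.00317 over 28 overlaps in 7 pairs of comparisons). DAC011A05 stood at -1.68 in the whole body and at 0.72 ± 0.139 (SE, limma adjusted p = 0.0499) in the CNS. Among probes with an unadjusted p under 0.05, 42 were positive in both (23.7 for independent lists, Fisher's exact test adjusted p = 0.00082), 36 negative in both (19.4, adjusted p = 0.00082), 40 negative in the whole body and positive in the CNS (20.2, adjusted p = 0.000121) and 15 the reverse (22.9, adjusted p = 0.212). The fru and the sex effects in the CNS, which would run together if FRUM accounted for the sex differences, had rho = -0.0284 over 6524 probes (jackknife SE 0.11). They shared 1 negative call, where independent lists would share 0.124, and 0 positive calls. With an unadjusted p under 0.05 in both, 29 probes were positive in both (8.49 for independent lists, Fisher's exact test adjusted p = 2.84e-08), 33 negative in both (21.5, adjusted p = 0.032), 27 positive for fru and negative for sex (11.6, adjusted p = 0.000169) and 19 the reverse (15.8, adjusted p = 0.549). These lists share each probe's estimate of the spread and so are not independent. With each experiment fitted alone they shared 34, 38, 40 and 13, against 10.2, 23.7, 13.3 and 18.2. Between fru in the whole body and sex in the CNS rho was 0.029 over 4716 probes (SE 0.1), with 0 shared calls. At an unadjusted p under 0.05, 43 probes were negative for fru and positive for sex (9.41 for independent lists, Fisher's exact test adjusted p = 5.59e-17) and 21 the reverse (17.2, adjusted p = 0.518). A further 3 were positive in both (10, adjusted p = 0.046) and 13 negative in both (16.1, adjusted p = 0.732). The relative direction is open here too. All of these are correlations across probes, which are not independent replicates.

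The RNAi comparisons asked what EcR-A, a nuclear receptor for the moulting hormone ecdysone, controls in cells that use the fru P1 promoter. In the CNS at 0 h, 22 of 5934 probes differed between RNAi and control males, all with a positive ratio, and 16 of them exceeded 2-fold. Probe DAC007K04 had the highest ratio, 2.65 ± 0.187 (SE, n = 4, 6.3-fold, limma adjusted p = 7.63e-06), with values of 4.46 and 4.55 in 1 dye orientation and 1.22 and 0.387 in the other. DAC002J17 had 2.02 ± 0.182 (SE, n = 3, 4.07-fold, limma adjusted p = 0.00269), with 3.61 on the only array of its dye orientation and 0.0309 and 0.838 on the others. The SE of DAC002J17 does not hold the gap between that array and the others. No probe passed with a negative ratio; DAC006B24, with the smallest p on that side, stood at -0.56 ± 0.122 (SE, n = 4, limma adjusted p = 0.0659), with -2.06 and -1.22 in 1 dye orientation and 0.512 and 0.514 in the other. Of the 22 calls, 17 had 1 sign on every array. Another limit is that 16 rested on 3 arrays, 1 of them alone in its dye orientation and so fitted exactly. Among probes with at least 2 values in each dye orientation, DAC007K04 was the only call. The count was 1 without replicate 1, 2 without replicate 2 and 4 without replicate 4, but each of these fits left 15 of the 22 untested for want of values and kept 1 of the 7 it tested. Without replicate 3 it was 48, among them 16 of the 19 calls it tested. Only 3 of the 22 became untested there, so most of these 19 had no value on replicate 3 and could hardly lose their call. This share is thus not comparable with the 1 of 7. The designed fit of 22 arrays called 7, and reading the ratios as Cy5 over Cy3 gave 482.

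In the adult brain 3 of 5992 probes passed, all with a positive ratio. DAC002K24 stood at 2.65 ± 0.208 (SE, n = 3, 6.27-fold, limma adjusted p = 0.0124), and DAC011C23 at 2.34 ± 0.148 (SE, n = 3, 5.05-fold, limma adjusted p = 0.00151). The third, DAC002J17, chosen for mention after its values were seen, stood at 1.68 ± 0.182 (SE, n = 3, limma adjusted p = 0.0135). DAC002J17 and DAC002K24 were also called at 0 h, where DAC002K24 had 1.82 ± 0.208 (SE, n = 3, limma adjusted p = 0.0207). These were the 2 adult calls among the 4853 probes tested at both times, where independent lists would share 0.00701 (Fisher's exact test p = 1.16e-05, adjusted p = 0.000323 over the 28 overlaps). The lists share each probe's estimate of the spread, however, and with each experiment fitted alone the 3 calls at 0 h and 1 in adults among these probes shared 0. The RNAi males carry a construct that the controls lack, and whether DAC002J17 or DAC002K24 measures a gene of that construct or its marker was not examined, because the probes are unnamed. Across these probes the effects at 0 h and in adults had rho = 0.265 (jackknife SE 0.28). Each of these adult calls took its highest value from replicate 1, the only array with a value in its dye orientation. Their SEs and p-values therefore do not measure the distance of replicate 1 from the other arrays. At an unadjusted p under 0.05 there were 227 adult probes, where chance alone would give 300; without replicate 2 the count of calls was 22, these 3 among them. With values on replicates 1, 3 and 4 only, they could not be tested with any 1 of those left out. The designed fit of 22 arrays called 0 (98 at an unadjusted p under 0.05 by limma), and reading the ratios as Cy5 over Cy3 gave 1836.

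**Figure D4:**
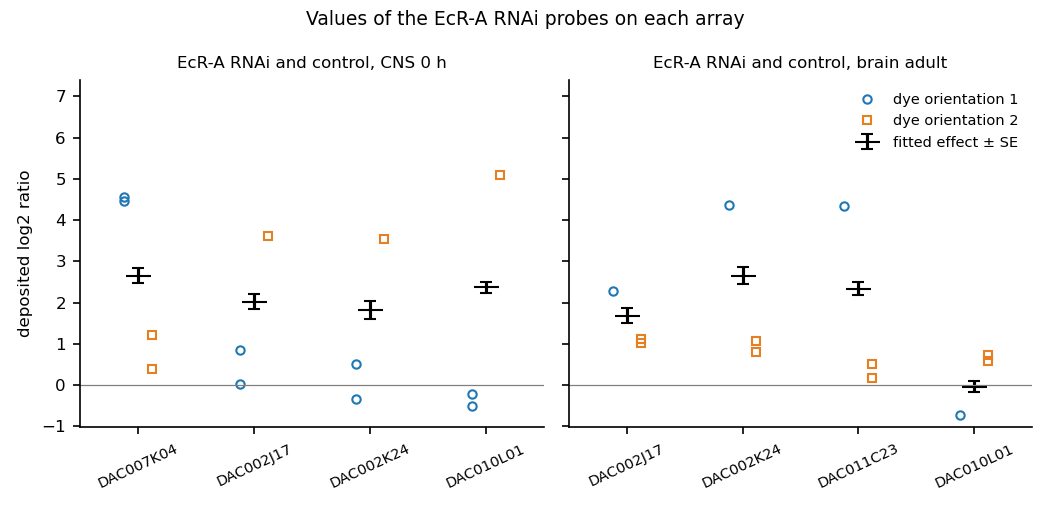
Deposited log2 ratio of probes called at 1 time or both in the EcR-A RNAi experiments at 0 h (left) and in adults (right), with 1 symbol per array, circles and squares for the dye orientations, and the fitted effect with its standard error in black. DAC002J17 and DAC002K24 were called at both times, and DAC010L01 at 0 h took 5.09 from 1 array against -0.506 and -0.216 on the others.

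In the brain at 48 h, 2 of 4302 probes passed, DAC037I16 and DAC011K23, both with a negative ratio (limma adjusted p = 0.0292 and 0.0375, n = 3). Their values ran down to -14.4 and -12.2 on replicate 4, on the unknown scale, and no fold is given. At an unadjusted p under 0.05 there were 113 probes, where chance would give 215, and the same fit called up to 3 probes in simulated data with none changed, a range that includes these 2. The count was 49 without replicate 1, the only array of this experiment on the log2 scale. It was 22 without replicate 3, with DAC037I16 and DAC011K23 among them (limma adjusted p = 1.52e-09 and 1.47e-07). Neither of these probes had a value on replicate 3, so their effects did not change in that fit. The lower p-values there do not come from the values of these probes and lend their calls no support. Without replicate 1, 2 or 4 neither had enough values to be tested. The fit over all 22 CNS and brain arrays called 1093.

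Between adult and 0 h the RNAi effect differed for 1 of 4853 probes, DAC010L01, at -2.41 ± 0.194 (SE, adult minus 0 h; limma adjusted p = 6.79e-05). This rested on 1 array at 0 h with a value of 5.09, alone in its dye orientation and so fitted exactly. With the 12 RNAi arrays fitted alone 0 probes passed (13 at an unadjusted p under 0.05 by limma, where chance would give 243). That fit holds the 3 arrays of unknown scale, which can raise its spread, so its 0 says little of this call. The count was 5 without adult replicate 1 and 3 without 0 h replicate 3, where DAC010L01 kept its call (limma adjusted p = 5.18e-05 and 4.76e-05). DAC010L01 had no value on either of these arrays, so its effect stayed at -2.41 and keeping the call was no test of it. With any other array of these experiments left out it had too few values to be tested. At an unadjusted p under 0.05 there were 144 probes, where chance would give 243. The counts of probes whose effect differed between 48 h and 0 h (311) and between adult and 48 h (147) compare values on different scales; both were 0 with the RNAi arrays fitted alone, where limma gave 539 and 459 at an unadjusted p under 0.05. Every array left out moved them. The difference between 48 h and 0 h passed for 1282, 61, 915 and 746 probes without replicate 1, 2, 3 or 4 of the 48 h experiment, and for 20, 35, 16 and 37 without replicate 1, 2, 3 or 4 at 0 h. That between adult and 48 h passed for 1232, 19, 752 and 740 probes without replicate 1, 2, 3 or 4 of the 48 h experiment, and for 7, 2, 0 (689 at an unadjusted p under 0.05 by limma) and 22 without those of the adult experiment.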

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

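The test of a stretched scale was chosen only after the result was seen, and the CNS estimate of the allele difference was added after seeing the data. The first pattern is the distance between the allele pairs in the whole body, where the fru effect differed for 1217 probes by a test of the difference itself, among them DAC037E21 with a difference of 4.22 (fru-440/fru-P14 minus fru-w12/fru-ChaM5), DAC032I05 with 3.81, DAC034F02 with -5.38 and DAC012O21 with -3.36. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1 gave as many, the real one, and the highest other gave 0. Every other split mixes arrays of both pairs, which raises the spread within its groups, so few calls were likely there. The splits thus show that the arrays of a pair resemble each other, not what sets the pairs apart. Unequal spread of the arrays is argued against by the 1416 probes that passed after every array was scaled to 1 spread. A slide or scan effect of the whole-body arrays may remain: the difference estimated in the CNS correlated with that in the whole body with Spearman's rho = 0.338 over the 398 called probes measured in both (jackknife interval 0.0789 to 0.598) and 0.0916 over all 3891 tested. This decides nothing, since pair and dye coincide in the CNS, the estimate there borrows its dye component from other experiments, and the relative direction of whole body and CNS is open, and the biological candidates, lesions and strain of the controls, were not separable here.

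The second pattern is the scale of the EcR-A RNAi arrays at 48 h. The effect differed between 48 h and 0 h for 311 probes and between adult and 48 h for 147. Of 34 splits of the 8 arrays, 9 and 11 gave as many, the highest others being 2744 and 2643, several times the real counts, which points to a structure of the arrays rather than the time points. A single stretching factor per array would keep the ranks of the dye component, as replicates 2 and 3 did (rho = 0.557 and 0.446, against 0.162 to 0.71 on the 18 log2 arrays), but replicate 4 stood at -0.117 (interval -0.15 to -0.0823), which argues against it for that array unless its sign was turned as well. What was done to these arrays stays open, and no biological explanation was tested.

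Between adult and 0 h the RNAi effect differed for 1 probe, DAC010L01, at -2.41, and 20 of 34 splits gave as many, the highest other being 29, so chance cannot be excluded. In the 0 h RNAi experiment replicate 1 had 5652 probes with a value against 6337 to 6455 on the others, a gap beyond Dixon's critical value, which 1 of 40 groups of values passed where chance would give 2.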

How the results depend on the processing

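The reading of ratios as Cy5 over Cy3 and the block on 8 arrays were chosen after seeing the data. So were the limits to probes with 2 values per dye orientation or with 1 sign. The same holds for the overlaps with each experiment or allele pair fitted alone and the fits of each allele pair. The 22-array fit was the design chosen before the data were examined. The 18-array fit replaced it because 3 arrays were not on a log2 scale. In the 22-array fit these 3 can raise the spread used for the other experiments, and the log2 arrays can lower that used for 48 h. Its counts are therefore not like for like with those of the other fits. Across 48 effects of named probes none of the 549 alternative values changed sign, 106 ended a call and 9 made one. Apart from the differences between allele pairs and between times, these probes were chosen for 1 sign on every array. Few changes of sign were thus likely, and their absence is no support for the calls. The reading as Cy5 over Cy3 was run for counts only, so the 549 values say nothing of named probes under it. The correlations between comparisons moved by less than their jackknife SE, and 1 changed sign: scaling to 1 spread took that of fru in the whole body with sex from 0.029 to -0.00262. The counts moved far more, and the cause was not tested except where fewer probes or arrays explain it. The 18-array and 22-array fits called 45 and 6 probes between the sexes, 64 and 1 for fru in the CNS, 22 and 7 for RNAi at 0 h, and 3 and 0 in adults. For RNAi at 48 h, 2 probes passed with its arrays alone, 1093 (591 positive, 502 negative) in the 22-array fit and 1342 with 1 dye coefficient shared there. Array number limits the precision, and signal over background is unknown. The limma fits below that called 0 probes had between 144 and 282 at an unadjusted p under 0.05 for RNAi at 0 h, 15 and 154 at 48 h, and 72 and 445 in adults.

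Without the dye coefficient the counts were 24 between the sexes, 66 for fru in the whole body, 4 for fru in the CNS and 0 for RNAi at 0 h, 48 h and adult. They were 162 in the fru-440/fru-P14 pair, 737 in the fru-w12/fru-ChaM5 pair, 625 for the difference between pairs, 127 between 48 h and 0 h, 0 between adult and 0 h, and 1 between adult and 48 h. With 1 dye coefficient shared by the CNS experiments they were 20 for fru in the CNS and 0 for RNAi at 0 h and adult. Read as Cy5 over Cy3, the ratios gave 794 probes between the sexes, 62 for fru in the whole body, 1941 for fru in the CNS, 482 for RNAi at 0 h, 0 at 48 h and 1836 in adults. These are counts of the component that follows the dye orientation. Between the sexes and in the whole body the strongest probes go against that reading, so 794 and 62 are not rival counts of sex or fru differences. In the other experiments the counts depend on the direction taken.

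Array weights gave 21 between the sexes, 249 for fru in the whole body and 322 for fru in the CNS. Centring on the median left 0 for RNAi at 48 h. Scaling to 1 spread gave 58 at 0 h (49 positive, 9 negative, against 22 and 0), 1 in adults, 806 in the fru-440/fru-P14 pair, 56 between 48 h and 0 h (16 positive, 40 negative, against 171 and 140), 3 between adult and 0 h, and 0 between adult and 48 h. Probes with a value on every array of the fit gave 5 between the sexes, 23 for fru in the CNS, 4 at 0 h, 0 at 48 h and 0 in adults. With no minimum number of arrays there were 69 between the sexes, 169 for fru in the CNS and 13 in adults. With at least 2 values in each dye orientation there were 14 between the sexes, 1 at 0 h, 0 at 48 h and 0 in adults. At an adjusted p under 0.1 limma gave 71 between the sexes, 197 for fru in the whole body, 160 for fru in the CNS and 35 at 0 h. Each experiment fitted alone gave 75 between the sexes, 36 for fru in the CNS and 4 at 0 h. For fru in the whole body a covariate for the allele pair gave 378, the fru-440/fru-P14 arrays alone 538 and the fru-w12/fru-ChaM5 arrays alone 823.

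The replicate numbers are not said to pair arrays, and the differences between same-numbered arrays of the 0 h and adult experiments correlated with r = -0.0823 and -0.00055. With the replicate number as a block on the 12 RNAi arrays the counts were 0 between 48 h and 0 h, 0 between adult and 0 h and 0 between adult and 48 h. They were 0 for all of these in the 12 arrays without the block too, and 0 between adult and 0 h with a block on the 8 arrays. At an unadjusted p under 0.05 limma gave 592, 1 and 474 with the block on 12 arrays, 539, 13 and 459 without it, and 49 with the block on 8 arrays. Between adult and 48 h the scaled arrays gave 287, and between adult and 0 h the fit without a dye coefficient gave 22.

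With each array left out in turn the counts ranged from 12 to 36 between the sexes, 45 to 110 for fru in the whole body, 17 to 200 for fru in the CNS, 1 to 48 for RNAi at 0 h, 0 to 49 at 48 h and 0 to 22 in adults. They ranged from 149 to 419 in the fru-440/fru-P14 pair, 827 to 1200 in the fru-w12/fru-ChaM5 pair, 765 to 1118 for the difference between pairs, 16 to 1282 between 48 h and 0 h, 0 to 5 between adult and 0 h and 0 to 1232 between adult and 48 h. With 4 arrays a probe with 3 values could not be tested once 1 of them was left out. All calls at 48 h, in adults and between adult and 0 h were of this kind, so a 0 there, or in the fits limited by the number of values, says nothing of these calls. Tests of gene lists, means over the probes of a gene and the check by roX RNAs were not run, because probes could not be named.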

Other observations

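The test of the sex-negative probes against fru P1 mutants, the test of the RNAi calls against the allele pairs the count of RNAi calls with 1 sign and the overlaps with each experiment fitted alone were chosen only after the result was seen. Probe DAC032I05, chosen for mention after its values were seen, had like signs in 2 CNS experiments: it stood at 0.86 ± 0.116 (SE, n = 6; limma adjusted p = 0.0047) between fru P1 mutants and wild type in the CNS and at 0.91 ± 0.142 (SE, n = 4; limma adjusted p = 0.0182) for RNAi at 0 h, with a positive value on all of these arrays. It was negative on all 4 arrays of the RNAi experiment at 48 h, between -2.73 and -0.104, where 3 arrays are on the unknown scale. On the only adult array with a value it stood at -1.25. Among probes with an unadjusted p under 0.05, 43 were negative for fru in the whole body and positive between the sexes in the CNS, where independent lists would share 9.41 (Fisher's exact test adjusted p = 5.59e-17 over 28 overlaps), and 3 were positive in both, against 10 (adjusted p = 0.046 by the same exact test). The relative direction of whole body and CNS is open, so like and opposite signs may be exchanged here (their dye components had r = 0.0494). For RNAi at 0 h and in adults 22 such probes were positive at both times, against 3.94 (adjusted p = 2.29e-10 by Fisher's exact test), and 6 with each experiment fitted alone, against 1.01 (adjusted p = 0.00103 over 8 overlaps by the exact test). Between fru in the CNS and RNAi at 48 h, 21 were positive in the first and negative in the second, against 4.56 (adjusted p = 1.36e-08 by Fisher's exact test). The RNAi effects at 0 h and 48 h had rho = -0.307 across probes (jackknife SE 0.18), those at 48 h and in adults -0.0878 (SE 0.31), and the fru CNS and 48 h RNAi effects -0.189 (SE 0.14). All relations with 48 h rest on 3 arrays of unknown scale and are not read as expression. At an unadjusted p under 0.05 the 48 h fit had 113 probes, where chance would give 215. Its effects also correlated with the mean dye component of the log2 CNS experiments, with rho between 0.237 and 0.255. Given that component the correlations were -0.302, -0.106 and -0.172.

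The third pattern is the 39 negative calls between the sexes. Over the 31 measured between fru P1 mutants and wild type in the CNS the median was 0.228 and 24 were positive, where random sets of probes gave a median of -0.106 to 0.0316. With the directions tied by the dye component this would go against dependence on FRUM, but with 1 experiment turned the median is -0.228 (random sets -0.0316 to 0.106) and would go with it, so dependence on FRUM stays open. RNA of another tissue carried along in dissection may contribute: over 14 arrays with male RNA in both channels the residuals of 22 of these probes had a mean pairwise correlation of 0.0683, within the 95th percentile of random sets (0.114) but above their median (0.00675), so it cannot be told apart from a difference in the CNS itself. Of the 39 probes, 79.5% could be tested in the fru CNS experiment (88% of all probes tested between the sexes), 43.6% for RNAi at 0 h (68.8%) and 33.3% in adults (68.4%), and neither this difference nor sex differences independent of FRUM were tested.

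Of the 22 RNAi calls at 0 h, 17 had the same sign on every array with a value, and 12 had a value beyond 2 log2 units on at least 1 array. Whether single extreme spots made these calls stays open. Of the RNAi calls at 0 h and in adults, 14 were measured in the whole body and 4 of them were among the probes that differed between the allele pairs, against 10.4% of other probes (odds ratio 3.43, interval 0.782 to 12, Fisher's exact test p = 0.0511).

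Swapping the channels of arrays, balanced over the dye orientations, left too few swaps for a share under 0.05 in most experiments. Between the sexes 1 of 3 swaps, the real one, gave as many as the 45 calls, and the highest other gave 6. For fru in the CNS it was 1 of 10, with 64 calls and 4 for the highest other. For RNAi it was 1 of 3 at each time, with 22 calls against 2 at 0 h, 2 against 0 at 48 h and 3 against 0 in adults. In the fru-440/fru-P14 pair (366 calls) and the fru-w12/fru-ChaM5 pair (1405 calls) it was 1 of 3, with 0 for the other swaps. For fru in the whole body 2 of 35 swaps gave at least the 101 calls, so chance was not excluded at a share of 0.05; the other was the swap that turns 1 allele pair, which called 732 and points to the difference between pairs as a structure of the arrays, and the remaining 33 gave 0.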
